A study of Petromyzon marinus with 2 samples.

How the data were processed

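Retinas of sea lamprey (*Petromyzon marinus*) at the downstream-migrant stage were snap-frozen, and nuclei were isolated with a kit, per the labels. A multiome library reads the nuclear RNA and the open chromatin (ATAC) of each nucleus under a shared barcode. Both libraries, replicates 1 and 2 of a single group, came from 1 suspension of nuclei, per the labels, so p-values measure only the technical spread between these 2 libraries and say nothing about differences between animals. The labels name no treatment, and all comparisons are between groups of nuclei found in the data.

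The deposited matrices hold counts: UMIs per gene and counts per accessibility peak for each barcode, made with Cell Ranger ARC 2.0.0, per the submitters' processing notes, on a lamprey transcriptome assembly extended with long reads, per the series' design text. The matrices were not filtered for nuclei. Replicate 1 held 714924 barcodes, 42038945 gene UMIs and 175390480 peak counts, and replicate 2 held 720812 barcodes, 37641637 gene UMIs and 160188451 peak counts. Of the nonzero peak counts 83.0% and 82.6% were even and 64.8% and 63.5% equalled 2, so a peak count was read here as a transposase insertion with mostly 2 per fragment, a reading that the labels do not state. The aligner settings and the genome build are not given in the sources used here; contig names are printed as the deposited features give them, and coordinates are 1-based. Peaks were called in each library separately, 95898 and 94960 of them with a median width of 860 bp.

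Of 20290 genes, 1958 had a symbol in the deposited features and 323 locus IDs took one from a reference gene table (assembly UKy_Petmar_22M1.pri1.0, used for names only). The remaining 8480 locus IDs and 9529 assembly IDs had none, so 11.2% of genes had a symbol and most retinal marker genes could not be looked up by name. The deposited positions give each gene an interval of starts. It spans over 10 kb for 7.01% of genes, and 26 of the genes in the promoter comparison have one over 2 kb. No genome was used, so sequence motifs in peaks were not analysed here, and with no mitochondrial contig among the features no mitochondrial filter was applied.

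A barcode was taken as a nucleus with at least 500 gene UMIs and at least 500 peak counts, which 11798 and 9793 barcodes reached. Scrublet (in scanpy 1.11.5, Python 3.11.15) with an expected rate of 8.0% called 1741 (14.8%) and 1258 (12.8%) of these doublets, which were left out. The nuclei kept, 10057 and 8535, held 50.5% and 50.3% of gene UMIs and 64.7% and 66.5% of peak counts. Gene UMIs were scaled to 10000 per nucleus and log-transformed. Genes of the held-out lists were removed before 3000 variable genes and 30 principal components were taken, with 15 neighbours (the nucleus itself included, scikit-learn 1.9.0) and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), without batch integration. Clusters were numbered by size. They were joined into groups by average linkage of their mean components (scipy 1.17.1), with the number of groups from 4 to 12 that had the highest silhouette (0.385 at 9 groups). Groups were lettered by size.

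Cell type markers were fixed before the data were examined, as were 12 held-out gene lists, the tests, the rule for named genes and most of the alternatives. Few markers matched a gene name: none of 16 for photoreceptors or 12 for ganglion cells, 2 of 14 for bipolar cells (NYX and LRTM1), 2 of 11 for horizontal cells (ONECUT1 and LHX1), 2 of 10 for amacrine cells (SLC6A9 and TH) and 2 of 13 for Müller glia (AQP4 and KCNJ10). Markers of retinal pigment epithelium matched 9 of 12, of endothelium 3 of 10 and of lens or cornea 3 of 9, and no gene name matched the microglial, pericyte, erythroid, myelinating or proliferating markers. A cell type name needed 3 markers of the type that passed as higher, which no group had. Photoreceptors, bipolar, horizontal, amacrine, ganglion and Müller glial cells had at most 2 matched markers. They could not reach this rule whatever the counts. Groups and clusters therefore carry no cell type name, and the intended comparison of rods with cones was not run. Clusters 1 and 5 were compared with cluster 2 instead, a choice made after the data were seen. No matched marker names these clusters rods or cones. Of the 12 fixed lists, those for bipolar, horizontal and Müller glial transcription factors, phototransduction, ribbon synapse, inhibitory transmission, and axon and spiking matched no gene name. Those for photoreceptor, amacrine and ganglion cell transcription factors, ionotropic glutamate receptors and glial metabolism matched some. A further 15 lists were added after gene names had been seen and before any count was read: transcription factors, peptide and monoamine signals, receptors, synapse and vesicle release, ion channels, cilium, retinoid handling, melanosome, glia-associated genes, secreted developmental signals, vascular and blood genes, extracellular matrix, cell division, ribosomal proteins and oxidative phosphorylation.

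UMIs were summed per library and group. Groups with at least 20 nuclei in each library entered 1 fit of edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3; TMM scaling, filterByExpr) with library as a block, since each library gave a sum for every group. Each group was compared with the mean of the other groups on the log2 scale. A gene passed with a Benjamini-Hochberg adjusted p under 0.05 over the 12916 genes tested and an absolute log2 fold change of at least 1. The 207 tested genes of the held-out lists, which took no part in clustering, are the results reported; a second adjustment covers these list genes alone. SE is the log2 fold change divided by the square root of the F statistic. CPM is the usual scaling of a count by the total gene UMIs of a library's group, and the CPM of the other groups is the mean of their CPM. The fold change is against the mean of their log2 levels, so it can exceed the ratio of the CPM printed. Where another group held no UMI of a gene, the fold change was recomputed with counts under 3 in a library set to 3 and is given as at least that value, or the CPM are given alone where they show a smaller ratio. The common biological coefficient of variation was 0.0319 for genes and 0.119 for regions.

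Named genes are, per group, up to 15 highest and 5 lowest by log2 fold change among list genes that passed and moved the same way in both libraries, up to 10 each way for the clusters, and the genes nearest to the 5 highest regions of each group. A further restriction was set after the values were seen: genes named as higher have at least 20 UMIs in each library and a CPM above that of the other groups, and those named as lower a CPM below it. Outside that rule, tested genes of the fixed lists that passed and the marker RPE65 are also named, chosen after their values were seen. The values of 1 tested gene are not reported here.

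Lists with at least 3 tested genes were tested with limma's camera (3.58.1) at a preset correlation of 0.01, 136 tests in all with Benjamini-Hochberg adjustment, and again with an estimated correlation and with fry. Peaks of both libraries were merged into 107289 regions, and counts were tested in the same way over the 83430 regions (77.8%) with a peak from each library. Promoter accessibility is the sum of peak counts within 2 kb of a gene's interval of starts, and its log2 fold changes were compared with those of RNA by Spearman's correlation with a two-sided permutation test of 100000 draws. Shares of nuclei have exact 95% binomial intervals, which cover counting error only. Neighbours in accessibility were the 16 nearest nuclei on 29 components of the peak counts. Free RNA was profiled from barcodes under 100 gene UMIs.

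The gene, region and list tests were tested on simulated data. For group A, 200 of 11735 simulated genes were changed: 100 of 100 were called at a log2 change of 1 and 100 of 100 at a change of 2, and 11 of 211 calls were false (5.21%). For regions 97 of 100 and 100 of 100 were called, with 4.83% of calls false. Gene and region calls in the simulated data used an adjusted p under 0.05 alone, without the fold threshold. At a change of 1 the median estimates were 0.997 for genes and 0.991 for regions, just below that threshold. How many would pass both thresholds was not counted. The changed genes and regions were drawn only from those above a minimum expected count in the smallest sum. All simulated genes shared 1 common spread, as did all regions. Recovery of less abundant genes, such as named genes with few UMIs in the other groups, was not tested. Camera called 20 of 20 raised lists and 1 of 100 unchanged lists. The simulated genes were drawn independently of each other, so this does not cover lists of correlated genes. The estimated correlation of the ribosomal list, for one, was 0.261.

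Alternatives covered the minimum counts per nucleus, barcode calling, doublets, resolution, components, variable genes, lists kept in the clustering, DESeq2 (1.42.0), no filter on low counts, no block, adjusted p alone, library totals, promoter windows, peak overlap and each library left out. Added after the data were seen were subtraction of free RNA scaled by the 50 genes highest in group B (so that nothing is subtracted from group B itself), upper-quartile scaling, fits without group H or without its cluster 53, recounts of the genes that passed with counts under 3 set to 3 (scaled by library totals) or by a CPM at least 2-fold from the mean CPM of the other groups, counts divided by 2 into fragments, regions of either library, tests per cluster, and promoter comparisons without ribosomal and oxidative phosphorylation genes or without long intervals of starts.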

Results

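Nuclei from frozen retinas of downstream-migrant sea lamprey, the newly metamorphosed animals that leave their stream, were profiled for RNA and open chromatin together. The labels give 1 group with 2 replicate libraries from a single suspension. Replicate 1 held 42038945 gene UMIs and 175390480 peak counts over all barcodes, and replicate 2 held 37641637 and 160188451. After filtering, 10057 and 8535 nuclei remained, with medians of 1681 and 1827 gene UMIs, 1083 and 1154 genes detected, and 10230 and 12200 peak counts per nucleus. The series' title concerns the conservation of regulatory codes across vertebrates; the question these libraries can address is which genes and accessible regions set the nuclei of the lamprey retina apart.

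The nuclei fell into 54 clusters and 9 groups, of which 8 (A to H) had enough nuclei to be compared. Group A held 29.0% of the nuclei of replicate 1 and 28.7% of those of replicate 2, with exact binomial 95% intervals of 28.1 to 29.9% and 27.8 to 29.7%. Group B held 26.9% and 26.8%, group C 16.4% and 16.5%, group D 9.53% and 9.47%, group E 7.47% and 8.05%, group F 7.06% and 6.53%, and group G 2.19% and 1.92%. Group H held 1.26% of replicate 1 (127 nuclei, interval 1.05 to 1.5%) and 1.93% of replicate 2 (165 nuclei, interval 1.65 to 2.25%), and these intervals did not overlap. The number of groups ranged from 8 to 12 over the settings tried. Some shares depended on them: group H held 3.63% and 6.63% with minima of 250 counts per nucleus and 0.158% and 0.44% with minima of 1000, where group G held 1.24% and 1.01%. With 15 principal components group E held 3.49% and 3.48% and group A 32.9% and 33.3%. With the 99th percentile of gene UMIs divided by 10 as the minimum, no group matched C or E. Group I, with 13 and 2 nuclei, was not compared. Group A was made of 22 clusters and group B of 3. Summed gene counts of the libraries correlated at Pearson's r of 0.988 for groups A and B and 0.844 for group H, across genes.

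**Figure D1:**
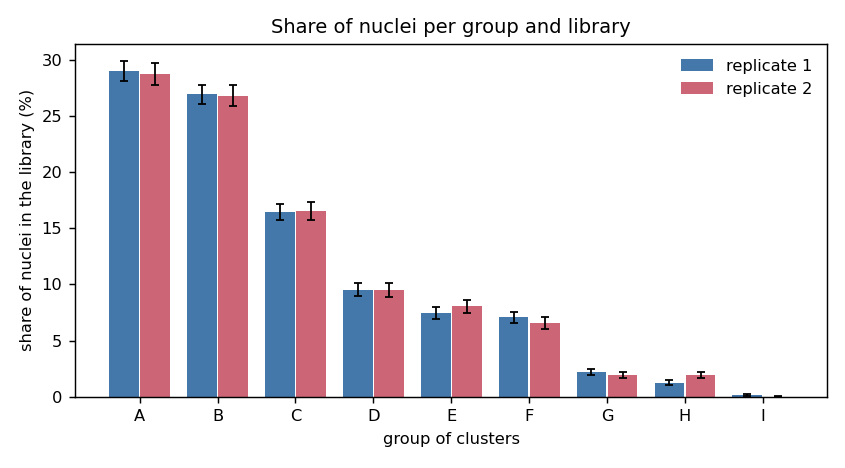
Share of nuclei (percent, y axis) in each group (x axis) for each library, with exact binomial 95% intervals as error bars. Groups A and B took 26.8 to 29.0% each in both libraries, and the intervals of group H (1.26% and 1.93%) lay apart.

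The genes named as higher in group A than in the mean of the other groups included FGB, CXCL14 and LAMA2. FGB, the beta chain of the clotting protein fibrinogen, reached 264 and 291 CPM in the libraries against 13.7 and 11.5 in the other groups. Its log2 fold change was 4.71 ± 0.09 (SE, n = 2 libraries), with an adjusted p of 1.24e-95 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cluster 6, 1 of the 22 clusters of the group, held 1564 of the 1801 FGB UMIs of group A in replicate 1 and 1616 of 1833 in replicate 2, and the FGB gene model has starts over 46156 bp, so other transcripts within it are not ruled out. The gene of the chemokine CXCL14 rose by 3.92 ± 0.22 on the log2 scale, and that of the laminin chain LAMA2 by 3.34 ± 0.12. GPR22, an orphan G protein-coupled receptor, rose by 2.95 ± 0.11, CDH23, a cadherin of hair cell tip links, by 2.77 ± 0.07, and SYT12, a synaptotagmin, by 2.72 ± 0.09. TH, the rate-limiting enzyme of catecholamine synthesis, stood at 21.7 and 21.9 CPM against 6.11 and 9.40. Cluster 11 held 98 of 148 and 103 of 138 TH UMIs of group A.

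By list, 52 of the 207 held-out genes rose in group A and 9 fell, beside 1714 and 607 of all 12916 genes tested. Adjusted over the list alone, 53 and 9 of the list genes did so. With counts under 3 set to 3 and scaling by library totals, 42 of the higher and 4 of the lower genes kept a log2 difference of at least 1, and 28 and 9 differed at least 2-fold in CPM from the mean CPM of the other groups. Both counts rest on the fold alone and were chosen after the data were seen. In synapse and vesicle release 11 of 21 members rose (camera, adjusted p = 2.65e-05; adjusted p = 0.0825 with an estimated correlation), and in receptors 5 of 14 rose (adjusted p = 0.00453 in camera; adjusted p = 0.109 with an estimated correlation). Of the secreted developmental signals 6 of 9 rose (adjusted p = 0.0373 in camera; adjusted p = 0.254 with an estimated correlation). In the fixed ganglion cell list 3 of 3 tested members rose, among them TBR1 by 1.91 ± 0.27 and FOXP2 by 1.12 ± 0.06. The list itself missed the threshold (adjusted p = 0.0698 in camera, and adjusted p = 0.254 with an estimated correlation). Subtracting free RNA, an alternative chosen after the data were seen, gave 80 higher and 7 lower of 211 genes. Group B, whose genes set the scale, had nothing subtracted. In group H 89.2% and 65.8% of gene UMIs were taken as free RNA, and group H is part of the mean for every other group. Its reduced counts can lower that mean, so calls gained or lost after subtraction cannot be tied to free RNA in the group named. The same limit holds for groups B to G below. The 9 lower genes became 5 with minima of 1000 counts per nucleus, 4 with scaling by library totals and 2 without group H in the fit.

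DDC, HYDIN and SPATA7 were among the genes higher in group B, and FOXP2, CAMKV and NETO2 among those lower. DDC, the decarboxylase that makes dopamine and serotonin, reached 248 and 232 CPM against 26.6 and 18.6, a log2 fold change of 4.13 ± 0.08 (SE, n = 2 libraries; adjusted p = 2.05e-93, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). HYDIN and CFAP54, genes of the central apparatus of motile cilia, rose by 3.61 ± 0.08 and 3.24 ± 0.16, SPATA7, a protein of the photoreceptor connecting cilium, by 3.07 ± 0.08, and WHRN, the scaffold protein whirlin, by 1.71 ± 0.10. The calcium-activated chloride channel gene ANO1 rose by 3.29 ± 0.08. The transcription factor gene FOXP2 fell by 3.38 ± 0.12, from 147 and 156 CPM in the other groups to 10.0 and 9.53. CAMKV, a kinase-like protein of synapses, fell by 3.51 ± 0.11, and NETO2, an auxiliary subunit of kainate receptors, by 3.37 ± 0.26.

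In all, 24 of 207 held-out genes rose in group B and 63 fell, beside 1834 and 2324 of all 12916 genes tested. The list counts were the same adjusted over the list alone. Of the list genes 14 and 63 kept the difference with low counts set to 3, and 15 and 63 by CPM. Of 22 cilium genes 10 rose and 2 fell (camera, adjusted p = 0.0455; adjusted p = 0.254 with an estimated correlation). Synapse and vesicle release had 2 higher and 11 lower of 21 (adjusted p = 0.000883 in camera; adjusted p = 0.0826 with an estimated correlation) and receptors 1 higher and 10 lower of 14 (adjusted p = 0.00089 in camera; adjusted p = 0.0825 with an estimated correlation). Transcription factors had 2 higher and 12 lower of 26 (adjusted p = 0.00164 in camera; adjusted p = 0.0825 with an estimated correlation), and extracellular matrix 1 higher and 8 lower of 13 (adjusted p = 0.00472 in camera; adjusted p = 0.34 with an estimated correlation). All 3 ionotropic glutamate receptor genes fell, GRIK5 by 3.08 ± 0.23, GRIK2 by 1.89 ± 0.10 and GRIN1 by 1.63 ± 0.07 (adjusted p = 0.0169 in camera; adjusted p = 0.254 with an estimated correlation). Without group H in the fit, and with nothing subtracted, 30 genes were higher and 69 lower. After subtraction of free RNA from the other groups, group H included, 46 genes were higher and 26 lower. CAMKV in group B (-2.02), NETO2 in group B (-2.19), GRIK5 in group B (-0.25) and GRIN1 in group B (-0.047) then no longer passed, GRIK2 in group B stood at 0.022, and FOXP2 in group B still passed at -3.30.

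CHRNA7, TRPC4, SYT12 and PRDM13 were among the genes higher in group C. CHRNA7, the alpha7 nicotinic acetylcholine receptor, reached 374 CPM in each library against 52.6 and 53.7, a log2 fold change of 3.23 ± 0.08 (SE, n = 2 libraries; adjusted p = 1.1e-76, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The cation channel gene TRPC4 rose by 3.50 ± 0.09 and the synaptotagmin gene SYT12 by 3.11 ± 0.10. PRDM13, a transcription factor of amacrine cell development in mice, rose by 3.0 ± 0.15 to 85.6 and 90.1 CPM against 23.4 and 22.6. TH stood at 40.2 and 33.3 CPM against 3.47 and 7.77, with 62 of 84 and 53 of 64 UMIs in cluster 22, and PODN, a matrix proteoglycan, at 46.4 and 37.0 CPM against 7.93 and 7.98. ZFHX3, a zinc-finger homeodomain factor, fell by 1.83 ± 0.13, and COL4A6, a chain of basement membrane collagen, by 1.64 ± 0.23.

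Group C had 51 higher and 15 lower of the 207 held-out genes, beside 1226 and 712 of all 12916 genes tested. The list counts were 53 and 15 adjusted over the list alone. With low counts set to 3, 43 and 13 kept the difference, and 27 and 15 by CPM. Synapse and vesicle release had 12 higher and 1 lower of 21 (camera, adjusted p = 1.13e-05; adjusted p = 0.0825 with an estimated correlation), receptors 7 higher of 14 (adjusted p = 0.00052 in camera; adjusted p = 0.0825 with an estimated correlation) and secreted developmental signals 7 higher of 9 (adjusted p = 0.00499 in camera; adjusted p = 0.168 with an estimated correlation). After subtraction of free RNA 73 genes were higher and 9 lower, and ZFHX3 in group C (-0.99) and COL4A6 in group C (-0.59) no longer passed. With minima of 1000 counts per nucleus 9 genes were lower.

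SKOR1, FEZF1 and KCNG3 were higher in group D. SKOR1, a transcriptional corepressor, reached 99.4 and 119.7 CPM against 2.21 and 0.782, a log2 fold change of 6.31 ± 0.21 (SE, n = 2 libraries; adjusted p = 1.82e-61, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the SKOR1 UMIs, 148 of 161 and 168 of 177 lay in cluster 3. FEZF1, a zinc-finger transcription factor of forebrain development, held 94 and 85 UMIs (58.0 and 57.5 CPM against 0.713 and 0.688), a log2 difference of at least 4.63. KCNG3, a modulatory potassium channel subunit, rose by 5.19 ± 0.18, the kainate receptor gene GRIK2 by 2.73 ± 0.06, and CADPS, which primes dense-core vesicles for release, by 2.40 ± 0.04 to 5333 and 5519 CPM against 1319 and 1289. FOXP2 fell by 1.85 ± 0.14 and GRIK5 by 1.84 ± 0.22.

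Across the lists 30 of 207 genes rose in group D and 31 fell, beside 1399 and 1062 of all 12916 genes tested. Adjusted over the list alone, 30 and 33 of the list genes did so. The difference held for 22 and 31 with low counts set to 3 and for 14 and 31 by CPM. The near balance of higher and lower genes thus depended on the measure. Ion channels had 6 higher of 18, extracellular matrix 5 higher and 4 lower of 13, and synapse and vesicle release 5 higher and 7 lower of 21, none of which camera called (lowest adjusted p = 0.583; the lists missed it with an estimated correlation too). After subtraction of free RNA 49 genes were higher and 27 lower, and GRIK5 in group D (-8.38) no longer passed the adjusted p threshold.

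Genes of receptors for dopamine and glutamate were among those higher in group E. DRD2, the D2 dopamine receptor, reached 251 and 244 CPM against 20.7 and 20.5, a log2 fold change of 4.42 ± 0.12 (SE, n = 2 libraries; adjusted p = 4.18e-74, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). GRM8, a metabotropic glutamate receptor, rose by 3.67 ± 0.06, GRIK5 by 3.09 ± 0.10 and GRIK2 by 3.08 ± 0.05, to 1541 and 1540 CPM against 326 and 337, with NETO2 higher by 3.85 ± 0.09. MYRIP, which links vesicle Rab proteins to myosin, rose by 4.42 ± 0.12 and PRDM13 by 3.65 ± 0.16. CENPE, a kinetochore motor of cell division, stood at 38.9 and 40.5 CPM against 2.77 and 3.28, at least 3.61 on the log2 scale, and was the 1 of 10 cell division genes that rose. Of its UMIs in group E, 47 of 49 and 51 of 51 lay in cluster 17. CADPS fell by 2.15 ± 0.06 and ANO4, an anoctamin membrane protein, by 3.31 ± 0.26.

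Group E had 36 higher and 16 lower of 207 held-out genes, beside 1134 and 891 of all 12916 genes tested. The list counts were the same adjusted over the list alone. Of the list genes 33 and 15 kept the difference with low counts set to 3, and 20 and 16 by CPM. Receptors had 9 higher and 2 lower of 14 (camera, adjusted p = 0.00075; adjusted p = 0.0825 with an estimated correlation), ionotropic glutamate receptors 2 higher of 3 (adjusted p = 0.00214 in camera; adjusted p = 0.175 with an estimated correlation) and synapse and vesicle release 8 higher and 3 lower of 21 (adjusted p = 0.00934 in camera; adjusted p = 0.152 with an estimated correlation). After subtraction of free RNA 53 genes were higher and 8 lower, and CADPS in group E (-0.50) no longer passed.

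PXDN, TBX2 and SLC10A4 were among the genes higher in group F. PXDN, the peroxidase that crosslinks basement membrane collagen, reached 414 and 458 CPM against 9.97 and 11.7, a log2 fold change of 5.73 ± 0.10 (SE, n = 2 libraries; adjusted p = 4.77e-102, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). TBX2, a T-box factor on the fixed photoreceptor list, rose by 4.22 ± 0.11 to 229.6 and 253 CPM against 15.2 and 15.6. SLC10A4, a transporter of synaptic vesicles, stood at 66.6 and 64.3 CPM against 0.747 and 1.39, at least 4.72 on the log2 scale. The synaptotagmin gene SYT16 rose by 4.06 ± 0.08, RAB27A, a GTPase of vesicle transport, by 4.19 ± 0.15, and the collagen genes COL7A1 and COL4A6 by 3.38 ± 0.11 and 3.31 ± 0.09. CHRNA7 fell by 2.73 ± 0.24.

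In group F 46 of 207 held-out genes rose and 27 fell, beside 1355 and 1107 of all 12916 genes tested. Adjusted over the list alone, 46 and 28 of the list genes did so. With low counts set to 3, 36 and 27 kept the difference, and by CPM 25 and 27, where higher genes no longer outnumbered lower ones. Transcription factors had 11 higher and 1 lower of 26, extracellular matrix 7 higher and 1 lower of 13, synapse and vesicle release 7 higher and 4 lower of 21, and retinoid handling 2 higher of 3. None of these lists was called, the closest being synapse and vesicle release (adjusted p = 0.0542 in camera) and extracellular matrix (adjusted p = 0.0645 in camera; adjusted p = 0.482 with an estimated correlation). After subtraction of free RNA 58 genes were higher and 8 lower, and CHRNA7 in group F (-2.42) no longer passed the adjusted p threshold.

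In group G, 220 and 164 nuclei, DACH1, CACHD1 and ANO4 were higher and GRIK2 was lower. DACH1, a factor of eye development, reached 609.7 and 702.6 CPM against 98.3 and 97.5, a log2 fold change of 3.38 ± 0.10 (SE, n = 2 libraries; adjusted p = 2.22e-67, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). CACHD1, a calcium channel subunit, rose by 4.8 ± 0.27, ANO4 by 4.12 ± 0.12 to 558 and 536 CPM against 49.7 and 49.6, NETO2 by 3.39 ± 0.14, and the ETS factor gene ETV1 by 2.89 ± 0.26. Cluster 36 held 228 of 228 and 183 of 184 ANO4 UMIs of the group, and 317391 of 408377 and 260710 of 343024 of all its gene UMIs. GRIK2 fell by 3.18 ± 0.20 and GRIK5 by 2.39 ± 0.38.

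Of the 207 held-out genes 25 rose in group G and 41 fell, beside 1320 and 1378 of all 12916 genes tested. Adjusted over the list alone, 26 and 42 of the list genes did so. Receptors had 2 higher and 8 lower of 14 (camera, adjusted p = 0.0252, and adjusted p = 0.175 with an estimated correlation). Peptide and monoamine signals had 3 lower of 6 and glia-associated genes 2 higher of 5. Camera called neither of these 2 lists (adjusted p = 0.211 and 0.173 in camera). After subtraction of free RNA 31 genes were higher and 13 lower, and GRIK2 in group G (-3.89) and GRIK5 in group G (-3.03) no longer passed the adjusted p threshold. The difference held for 25 higher and 28 lower genes with low counts set to 3 and for 17 and 40 by CPM.

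Group H stood apart by ribosomal protein genes. All 32 tested ribosomal protein genes rose, with a median log2 fold change of 3.71 (camera, adjusted p = 4.5e-20; adjusted p = 0.109 with an estimated correlation). The level was uneven within the group: the median ribosomal protein gene stood at 1701 and 2583 CPM in cluster 53 (11 and 10 nuclei) and at 160 CPM in each library in cluster 34 (86 and 119 nuclei). With cluster 53 left out, an alternative chosen after the data were seen, all 32 rose with a median of 3.10. RPS28 reached 354 and 378 CPM against 19.7 and 17.7, a log2 fold change of 4.59 ± 0.16 (SE, n = 2 libraries), and RPL38 rose by 4.53 ± 0.13. Of 15 oxidative phosphorylation genes 10 rose, with a median of 1.69 (adjusted p = 6.87e-05 in camera; adjusted p = 0.0825 with an estimated correlation). GATA2, a transcription factor of blood and vessel cells, held 44 and 37 UMIs (136.5 and 110.1 CPM), at least 6.29 on the log2 scale, and was not called by DESeq2. Synapse and vesicle release had 2 higher and 11 lower of 21 (adjusted p = 0.00613 in camera; adjusted p = 0.137 with an estimated correlation), among them CAMKV, which fell by 2.11 ± 0.19.

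In group H 72 of 207 held-out genes rose and 29 fell, beside 2301 and 1335 of all 12916 genes tested. Adjusted over the list alone, 73 and 31 of the list genes did so. The difference held for 69 and 26 with low counts set to 3 and for 61 and 29 by CPM. Further, 4 of 10 cell division genes, 4 of 9 vascular and blood genes and 2 of 4 melanosome genes were among the higher, in lists that camera did not call (lowest adjusted p = 0.277). RPE65, a retinal pigment epithelium marker that took part in the clustering, held 21 and 2 UMIs in this group, 65.1 and 5.95 CPM. It is 1 of 9 matched markers of that type, picked after its values were seen. No group had 3 that passed as higher, so RPE65 does not name group H. The nuclei of group H had medians of 2848 and 2340 peak counts against 10230 and 12200 over all nuclei. Genes enriched in group B stood in group H at 89.2% and 65.8% of their level in free RNA, against 5.93 to 15.1% in groups A and C to G. The subtraction of free RNA took these values as the shares of gene UMIs that were free RNA. On that reading most gene UMIs of group H were free RNA, so its calls may not reflect its nuclei alone. The count of lower genes was 18 with DESeq2 and 59 after subtraction of free RNA.

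The ribosomal list was called lower in groups A (camera, adjusted p = 5.55e-11), C, D, E, F and G, with medians of -0.75, -0.54, -0.69, -0.53, -0.46 and -0.83, at adjusted p of 0.252 to 0.482 with an estimated correlation. Group H is part of the mean these groups were compared with, and without it the medians were -0.20, -0.03, -0.19, 0.03, 0.04 and -0.32. In groups A and C the ionotropic glutamate receptor list was called higher with 1 of 3 genes rising in each, GRIK5 in group A and GRIK2 in group C, the latter at 0.95 without group H (adjusted p = 0.0148 and 0.0291 in camera; adjusted p = 0.254 and 0.281 with an estimated correlation). No list call held with an estimated correlation: of 136 tests 0 passed in either direction, 15 higher and 10 lower had an unadjusted p under 0.05, camera at the preset correlation called 14 higher and 13 lower, and fry called 48 and 52. With library totals in place of TMM the median log2 fold change of all genes was 0.16 in group A, -0.18 in group B, 0.22 in group C and -0.31 in group H.

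The lists fixed before the data were examined came down to 9 tested genes, all of transcription factors or ionotropic glutamate receptors, among them FOXP2, GRIK2, GRIK5, GRIN1, PRDM13, TBR1, TBX2 and ZFHX3. In group A 5 passed, all higher, in group B 8 passed, all lower, in group C 3 rose and 2 fell, in group D 1 and 2, in group E 4 and 1, in group F 6 and 2, and in groups G and H 1 and 4, each with the same counts adjusted over the list alone. Of the higher genes, 4 in group A, 2 in group C, 1 in group D, 3 in group E and 3 in group F differed at least 2-fold in CPM, and the 1 in group G and the 1 in group H did not. With low counts set to 3, the 1 higher gene in group H and 1 of the 4 lower genes in each of groups G and H missed a log2 difference of 1. As the log2 ratio of CPM, FOXP2 in group A was at 0.53, GRIK2 in group C at 0.037 and ZFHX3 in group E at 0.98. PRDM13, from the amacrine list, rose in groups C and E. It fell by 1.35, 1.36 and 2.05 in groups B, F and H, calls that subtraction of free RNA (0.055 for PRDM13 in group B, -1.20 for PRDM13 in group F) or DESeq2 (-1.94 for PRDM13 in group H) ended; without replicate 2 PRDM13 in group B stood at -0.96, and without replicate 1 PRDM13 in group H stood at -0.97. ZFHX3, from the same list, rose in group A by 2.33 ± 0.06, in group E by 1.72 ± 0.09 and in group F by 1.97. The glial metabolism list had GLDC and CYP26A1 as its matched genes, and neither was among the genes tested.

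**Figure D2:**
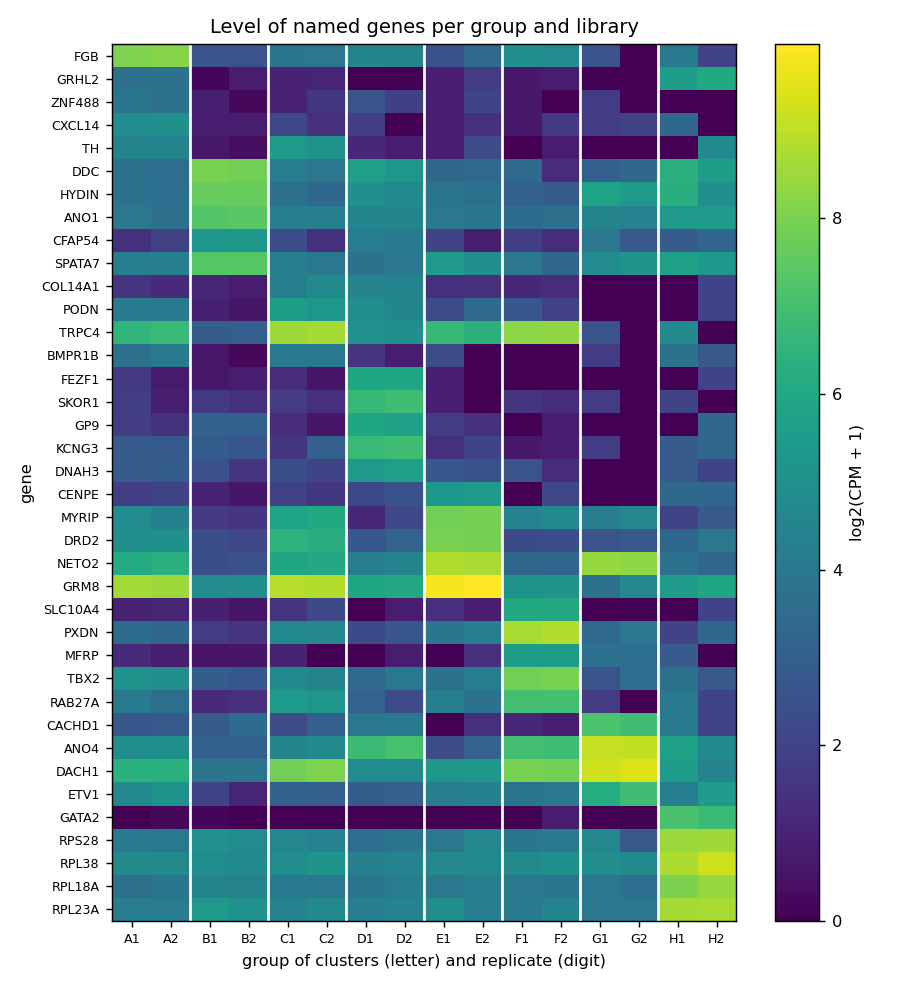
Levels of named held-out genes as log2(CPM + 1) on the colour scale, with genes on the y axis and each group (letter) and library (digit) on the x axis. FGB was highest in group A (264 and 291 CPM), DDC in group B (248 and 232 CPM), DRD2 in group E (251 and 244 CPM), PXDN in group F (414 and 458 CPM), ANO4 in group G (558 and 536 CPM) and RPS28 in group H (354 and 378 CPM).

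Within group B, clusters 1 and 5 were compared with cluster 2, which made up 13.0%, 3.38% and 10.5% of the nuclei of replicate 1 and 13.1%, 3.27% and 10.5% of those of replicate 2. DDC was higher in clusters 1 and 5, at 304 and 295 CPM against 97.5 and 89.4, a log2 fold change of 1.64 ± 0.07 (SE, n = 2 libraries; adjusted p = 5.04e-28, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), as were the ribosomal protein genes RPL22 (1.49 ± 0.13) and RPS14 (1.37 ± 0.09). DNAH10, an axonemal dynein of motile cilia, fell by 4.27 ± 0.28, from 32.8 and 42.2 CPM in cluster 2 to 2.26 and 3.45. SYT12 fell by 2.11 ± 0.19, GRIK2 by 1.54 ± 0.11 and CADPS by 1.22 ± 0.03, from 4101 and 4250 to 1836 and 1845 CPM. Of 138 held-out genes 13 rose and 14 fell, beside 586 and 620 of all 10495 genes tested. Of 71332 regions 5316 were more and 6112 less accessible in clusters 1 and 5.

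Groups defined by RNA were compared with neighbours in accessible chromatin. Of the 16 nearest neighbours of a nucleus in accessibility alone, 92.9% and 93.2% on average belonged to the same group for group A, 98.9% and 98.9% for group B, 94.7% and 94.6% for group C, 97.3% and 96.9% for group D, 88.4% and 89.7% for group E, 92.9% and 93.1% for group F, 95.9% and 93.2% for group G, and 63.0% and 67.1% for group H, which held 1.57% of all nuclei. Peaks of replicate 1 overlapped a peak of replicate 2 in 87.1% of cases, and those of replicate 2 in 87.9%. Of the 83430 regions with a peak from both libraries, 30.2% lay within 2 kb of a gene start and 49.2% over 10 kb away.

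Group B had the most regions that differed, 17627 higher and 22820 lower of 83423 tested (edgeR's quasi-likelihood test). Group A had 13258 higher and 4361 lower, group C 13305 and 8218, group D 13052 and 12776, group E 11872 and 8608, group F 14043 and 4961, group G 8856 and 13839, and group H 9784 and 6351. Depth differed between the groups, with 39612163 and 34514450 peak counts in group B against 920906 and 816419 in group H. The numbers of regions therefore do not rank the groups by how far they differ. The higher regions lay over 2 kb from a gene start in 73.1% (group B) to 80.5% (group C) of cases, against 69.8% of all regions tested, and of the regions lower in group H 43.4% did. With library totals in place of TMM, group B had 13265 higher and 29357 lower and group H 11906 and 3677; DESeq2 gave 15926 and 4499 for group H.

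**Figure D3:**
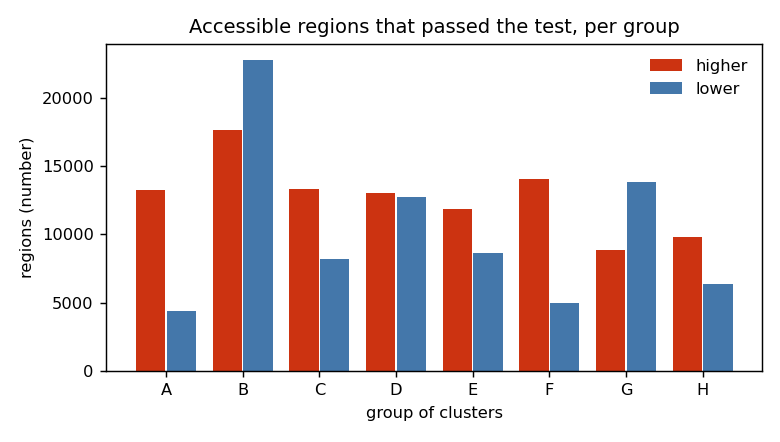
Number of accessible regions (y axis) that were higher or lower in each group A to H (x axis) than in the mean of the other groups, of 83423 tested, from the sums of 2 libraries. Group B had 17627 higher and 22820 lower regions, and group F 14043 and 4961. The groups differ in summed peak counts, so these numbers do not rank them.

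Of the 77 pairs of a group from A to G and a gene named as higher in it, 70 had a tested region within 10 kb of the gene and 61 had at least 1 that was more accessible in the same group, by edgeR's quasi-likelihood test. In group H 5 of 6 pairs had a region and 2 a more accessible one. CENPE and MYRIP in group E, COL14A1 in groups C and D, DNAH3 in group D, BMPR1B in group A and CFAP46 in group C were among those with regions that did not pass as higher. Of all regions tested, 10.6% (group G) to 21.1% (group B) were higher in groups A to G. Some genes had many regions, such as CADPS with 45, so a higher one is likely for such genes anyway. No rate for other genes is given here. Each region printed below for a gene named as higher is its more accessible region of highest fold change. In group B a region at NC_046090.1 from 1451036 to 1451951, near DDC, rose by 4.30 ± 0.26 on the log2 scale (SE, n = 2 libraries), and 6 of the 6 regions within 10 kb of the gene were higher. In group A the region NC_046091.1 from 1061073 to 1061991 near LAMA2 rose by 3.58 ± 0.14, with 4 of 4 regions higher. Near TH the region NC_046075.1 from 16530793 to 16531562, 6613 bp from the gene start, rose in group C by 3.55 ± 0.33 and in group A by 2.62 ± 0.36. Near PRDM13, 4 of 4 regions were higher in group C and 4 of 4 in group E, with the highest fold change at NC_046128.1 from 8080264 to 8081117 in group C (4.04 ± 0.35) and from 8072298 to 8073044 in group E (3.74 ± 0.44). In group D the region near FEZF1 (NC_046098.1, 1150591 to 1151529) rose by 5.90 ± 0.26, that near SKOR1 (NC_046069.1, 26829570 to 26830497) by 3.93 ± 0.27 and that near KCNG3 (NC_046074.1, 5265244 to 5266200) by 3.04 ± 0.20.

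In group E the region near GRIK5 (NC_046100.1, 12591391 to 12592204) rose by 3.34 ± 0.21 and that near DRD2 (NC_046100.1, 7783227 to 7784102) by 2.80 ± 0.21. In group F the region near TBX2 (NC_046106.1, 618480 to 619208) rose by 3.07 ± 0.25 and that near SLC10A4 (NW_022638112.1, 29232 to 30041) by 3.76 ± 0.26, and in group G that near DACH1 (NC_046086.1, 7531920 to 7532998) by 3.96 ± 0.17 and that near ETV1 (NC_046070.1, 17746881 to 17747489) by 3.52 ± 0.36. Among the 5 regions with the highest fold changes of each group, few had a named gene nearest to them: 1 in group A, at NC_046069.1 from 16193805 to 16194723, lay 17423 bp from ADPGK (5.14 ± 0.49), and 1 in group G, at NC_046081.1 from 2060077 to 2060976, lay 45346 bp from ONECUT1, a transcription factor gene of horizontal cells in other vertebrates (5.92 ± 0.19).

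Promoter accessibility and RNA of the held-out genes moved together in groups A to G. Across 170 genes, which are not independent replicates, Spearman's rho between the log2 fold changes was 0.679 in group A, 0.807 in group B, 0.595 in group C, 0.606 in group D, 0.605 in group E, 0.630 in group F and 0.502 in group G (two-sided permutation test with 100000 draws, p = 1e-05 for each, the smallest the draws can give; Benjamini-Hochberg adjusted p = 1e-05 over the 8 groups). Of the genes past the RNA threshold, promoter accessibility had the same sign for 42 of 47 in group A, 71 of 74 in group B and 48 of 56 in group G. In group H rho was -0.00348 (permutation p = 0.963, adjusted p = 0.963), with the same sign for 47 of 87. Without the ribosomal protein and oxidative phosphorylation genes, an alternative chosen after the data were seen, rho in group H was 0.313 across 123 genes (permutation p = 0.00046, adjusted p = 0.00046).

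**Figure D4:**
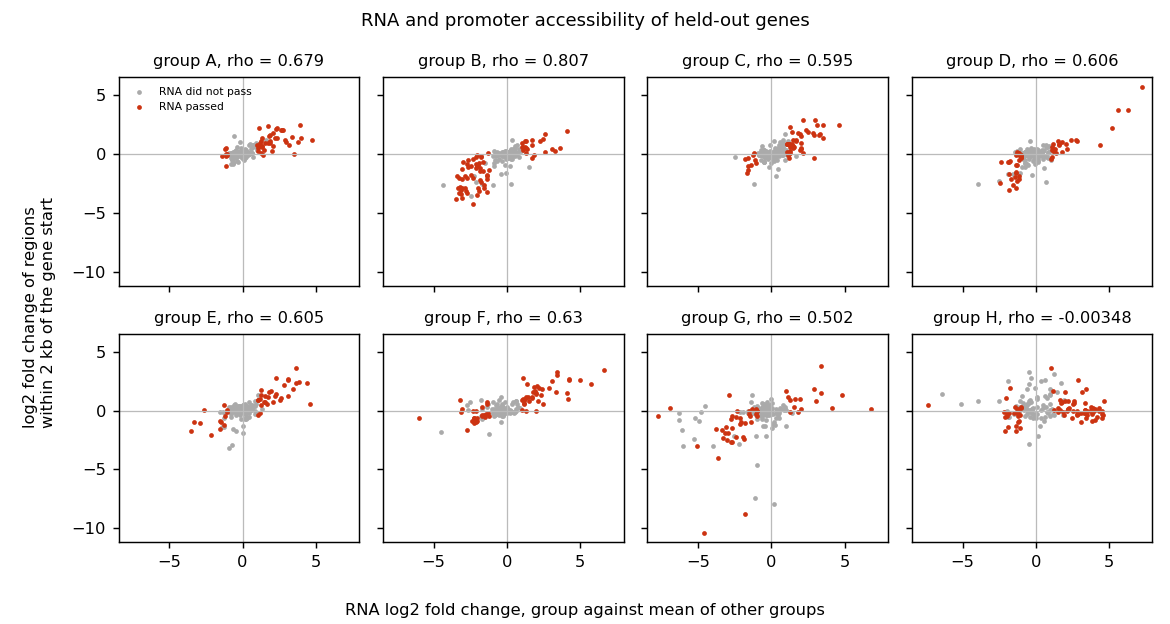
Promoter accessibility (log2 fold change, y axis) against RNA (log2 fold change, x axis) of 170 held-out genes in each group against the mean of the other groups, 1 point per gene and 1 panel per group. Spearman's correlation was 0.807 in group B and -0.00348 in group H.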

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

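The signal below was looked for only after the matrices had been seen, and no explanation of it was tested. Barcodes with at least 500 gene UMIs but under 500 peak counts were left out as nuclei, 1525 in replicate 1 and 1096 in replicate 2. Only the clustering with minima of 250 counts took in some of them, and no gene or region test used their RNA. Their medians were 1316 and 1297.5 gene UMIs and 187 and 186 peak counts. Their summed log2 CPM correlated with that of the nuclei at Pearson's r of 0.988 and 0.979 across genes. Ribosomal protein genes took 0.179% and 0.201% of their gene UMIs, against 0.167% and 0.168% in the nuclei.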

How the results depend on the processing

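Among the tests of settings, those chosen only after the result was seen were free RNA subtraction, upper-quartile scaling, fits without group H or without its cluster 53, low counts set to 3, the ratio of CPM, fragments, regions of either library, tests per cluster, clusters 1 and 5 against cluster 2, and the 2 restricted promoter comparisons. Over all settings, the values of named genes kept direction and call in 2070 cases, lost the call in 104 and changed sign in 6. Those of named regions kept both in all 315 cases. Settings with no test were each library left out, low counts set to 3 and the ratio of CPM. In these the log2 threshold of 1 alone stood for the call. Of the summary values 429 stayed within 1.5 times or on their side of the threshold, 81 moved further and 1 passed newly. Of the group shares, each of 1 group and library in 1 setting, 115 stayed within their intervals and 51 moved beyond. The cause of a move was not tested unless stated.

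With the 99th percentile of gene UMIs divided by 10 as minimum, 3290 and 3866 nuclei were called and 91.0% of those shared stayed in the matched group, but no group matched C or E, group A took 36.6% and 43.3%, and the adjusted Rand index was 0.5615. With 15 components there were 33 clusters and 94.998% stayed (index 0.744), with group A at 32.9% and 33.3% and group E at 3.49% and 3.48%. Others kept 99.7% (resolution 0.5; index 0.850, 10 groups), 99.98% (resolution 2; 0.8445, 12 groups), 99.7% (1500 variable genes; 0.889, 11 groups), 99.9% (lists kept in clustering; 0.834, 12 groups), 99.7% (minima of 250; 0.8405, 12 groups), 99.6% (minima of 1000; 0.994, 8 groups) and 99.6% (no doublets removed; 0.8455, 12 groups). Each library alone kept 97.9 to 98.9% (index 0.948 and 0.980, 8 groups). Several new groups can match 1 group, so the percent does not count a group that was split and the index does.

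Free RNA subtraction gave 80 higher genes in group A, 46 higher and 26 lower in B, 9 lower in C, 49 higher in D, 8 lower in E, 8 lower in F, 13 lower in G and 59 lower in H. GRIK2 in group B (0.022), PRDM13 in group B (0.055) and ZFHX3 in group G (0.28) changed sign. Group H, which lost most to the subtraction, is part of the mean for groups A to G. These changes therefore cannot be tied to free RNA in the group named. Minima of 1000 gave 5 lower genes in A and 9 in C, and no value for group H. Lower genes in A numbered 4 with library totals and 2 without group H, and lower genes in H 18 with DESeq2.

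Of the genes that passed, counted again by the fold alone, 4 lower in A and 14 higher in B kept a log2 difference of at least 1 with low counts set to 3. In CPM at least 2-fold above the mean of the other groups were 28 in A, 15 in B, 27 in C, 14 in D, 20 in E and 25 in F. With low counts set to 3, DNAH3 in group G (0.31), CACNG3 in group H (0.038) and MMP2 in group H (0.39), with 0 UMIs in these groups, changed sign. Named pairs with 0 UMIs in the group had no log2 ratio of CPM.

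Adjusted p alone has no fold threshold and so called more: genes lower in A 49, higher in B 52, lower in C 52, higher and lower in D 47 and 58, lower in E 47, lower in F 59, and 39 and 24 for clusters 1 and 5 against cluster 2. For regions it gave 21421 and 11782 in A, 30458 higher in B, 21242 and 12602 in C, 22572 higher in D, 19170 higher in E, 11357 lower in F and 10272 lower in H. DESeq2 gave 15926 regions higher in H, and library totals 3677 lower. List tests gave 0 and 0 with an estimated correlation, where camera left 15 and 10 at an unadjusted p under 0.05, and 48 and 52 with fry. Spearman's correlation in H was 0.313 without ribosomal and oxidative phosphorylation genes. Peak sharing was 86.9% and 87.7% at an overlap of 0.5 of both peaks, and 97.5% and 97.9% for peaks with counts at or above the median.

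Leaving out each library gives fold changes with no test, counted on the fold threshold alone. Genes lower numbered 18 to 24 in C, 42 to 52 in D, 29 to 38 in E, 42 to 47 in F, 88 to 92 in G and 59 to 61 in H, and 1028 to 1042 over clusters against 362. Regions lower in G numbered 26157 to 26228, and in H 19541 to 19815 were higher and 20479 to 22872 lower. Fits with no replicate block kept every named call and gave 24 higher and 41 lower genes in G and 72 and 30 in H.

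Not run were the mitochondrial filter, free RNA scaled by photoreceptor markers, the 3 motif alternatives and the comparison of named rods with cones. The 15 added lists were chosen after the gene names were seen and before any count was read. Groups G and H had 220 and 164 and 127 and 165 nuclei, and the simulated data covered group A alone, so how many changes were missed in them was not tested.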

Other observations

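The tests per cluster, and those of doublets of a pair of nuclei of cluster 1, of yield, of free RNA in cluster 34 and of the FGB gene model, were chosen only after the result was seen. Over 50 clusters, each against the mean of the others, edgeR's quasi-likelihood test called 1135 of 8050 pairs of gene and cluster higher and 362 lower. Every pair named in this and the next paragraph was called higher. CPM are given in place of fold changes, since some clusters held 0 UMIs of most of these genes. TH stood at 203 and 224 CPM in cluster 11 of group A (2.26% and 2.36% of nuclei), against 19.0 and 12.4 in the other clusters. In cluster 22 of group C (1.46% and 1.61% of nuclei) it stood at 289 and 257 CPM, with CHRNA7 at 812 and 743 CPM and BMPR1B at 121 and 107. In group A, CXCL14 was highest in cluster 10 (218 and 223 CPM), ROR1, a receptor of Wnt ligands, in cluster 18 (550 and 533 CPM) and LAMA2 in cluster 42 (999 and 796 CPM). In group C, COL14A1 was highest in cluster 24 (155 and 209 CPM) and FOXP2 in cluster 39 (1998 and 2102 CPM).

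In group D, SKOR1 was highest in cluster 3 (164 and 207 CPM against 3.29 and 1.49 in the other clusters). FEZF1 was higher in cluster 9 (114 and 95.5 CPM) and cluster 29 (169 and 209 CPM), as was KCNG3 (184 and 198, and 132 and 175 CPM). In group E, CENPE was highest in cluster 17 (137 and 135 CPM against 2.47 and 3.06) and MYRIP in cluster 37 (835 and 807 CPM). In group G, ANO4 (718 and 702 CPM) and CACHD1 (158 and 134 CPM) were highest in cluster 36. In group H, GATA2 held 238 and 343 CPM in cluster 48, against 1.92 and 0.821 in the other clusters. DDC, high in group B, was also higher in cluster 45 of group A (175 and 169 CPM against 33.2 and 28.2), where mean doublet scores of 0.0664 and 0.073 against 0.0447 and 0.0458 in group A leave doublets with group B nuclei open.

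Ribosomal protein genes were high in group H, with a median of 329 and 379 CPM, and uneven within it: 160 and 160 CPM in cluster 34, 310 and 364 in cluster 48 and 1701 and 2583 in cluster 53. Free RNA would need a level as high, and barcodes under 100 gene UMIs had 92.1 and 99.5 CPM, so that group H as a whole stood at least 3.57 times higher. In cluster 34, which held 86 and 119 of the 127 and 165 nuclei, the ratio was 1.73 ± 0.184 and 1.61 ± 0.156 (bootstrap SE over genes), too close to the bound of 1.5 set for this test, so free RNA in that cluster stays open. The ribosomal protein genes with a symbol took at most 1.38% of gene UMIs, which argues against these genes taking most of the counts. The share says nothing of other abundant genes, and most genes had no symbol. No biological explanation was tested, since the labels give no groups to compare.

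FGB was high in cluster 6 of group A, at 1168 and 1218 CPM. Free RNA reached at most 5.87% of that level, which argues against free RNA as the source. The regions within 2 kb of the FGB interval of starts were more accessible in the cluster by 2.49 on the log2 scale. The rise was largest in the regions 32001 and 33251 bp from the lowest start, and smaller in those at 12442 and 18192 bp. Accessibility within so long an interval cannot be tied to FGB itself, so it does not decide whether FGB RNA was made in these nuclei. The FGB gene model spans 46156 bp of starts, so its UMIs may come from another transcript within it, and no value here tells these apart, since UMIs are summed per gene. No biological explanation was tested.

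Cluster 5 resembled cluster 1 with more counts per nucleus: medians of 5660.5 and 4972 gene UMIs against 1473.5 and 1601.5, with 37 higher and 9 lower of 10495 genes. Doublets with nuclei of other groups would raise genes of groups A, C, D, E and F, whose median log2 fold change was -0.062 ± 0.0098 (bootstrap SE, 1343 genes). This value does not cover doublets with nuclei of cluster 2, which is in group B too, and these were not tested. A higher yield of both readouts alike, or doublets of a pair of cluster 1 nuclei, would leave the makeup of the RNA as it was, yet the median log2 fold change of 32 ribosomal protein genes was 0.34 ± 0.057 (bootstrap SE) against -0.0012 for all genes, which argues against either as the whole cause. Of these, 31 had a log2 fold change above 0 and 11 an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the highest, RPS12 at 0.73, was below the log2 threshold of 1. Yield or doublets as part of the cause stay open, with UMI ratios of 3.84 and 3.10 beside peak count ratios of 3.13 and 2.43 and mean doublet scores of 0.0516 and 0.0447 against 0.0345 and 0.0377 in cluster 1, and no biological explanation was tested.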
